A study of Mus musculus with 18 samples.

How the data were processed

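Retinas of ICR mice, an outbred stock, were electroporated at postnatal day 0.5 with a knockdown or overexpression plasmid together with an EGFP plasmid and kept as explants for 3 days, per the labels' protocols. EGFP-positive cells were sorted by FACS, cDNA was made from 1 ng of total RNA with SMART-Seq v4, and libraries were made with the Nextera DNA Flex kit, per the labels' protocols. This chemistry does not mark the strand, so that reads of overlapping and antisense genes cannot be told apart. The 18 samples formed 6 groups of 3 by their labels. Scramble, Nmnat1 knockdown and Nmnat2 knockdown samples filled one table, and empty vector, Nmnat1 overexpression and Nmnat2 overexpression samples filled another. The titles of 1 sample in the Nmnat2 knockdown group and 1 in the Nmnat2 overexpression group name Nmnat3, whereas their descriptions and characteristics name Nmnat2, and the latter were followed. The columns of the knockdown table show the group of each library but are not spelled as any one sample, and are called here by their column names (C1 to C3, N1_1 to N1_3, N2_1 to N2_3). All columns were used.

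Salmon 0.11.3, sleuth 0.30.0 and the genome build GRCm38.p6 are named in the submitters' processing notes, without role or order. The deposited values are named TPM, but the columns summed to between 14.4 and 29.6 times 1000000 in the knockdown table and between 17.3 and 26.2 times 1000000 in the overexpression table, so they were treated as a length-scaled expression signal that the authors had computed in a unit not given in the sources used here. In genes with 1 annotated transcript in the GENCODE release given next, low values of the deposited signal lay on steps of 1 read: with a tolerance of 0.1, between 74.7% and 85.8% of them per library were near a whole multiple of what 1 read would be worth, where 20% would be by chance and 16.4% to 22.3% were after lengths had been shuffled over genes. The other genes have no single length, so that whole reads were not recovered for nearly all genes and no count test was run. The steps gave the relative depth of the libraries of a table, as the reads summed over 9196 and 9201 such genes divided by the median library. Total read numbers are not given in the sources used here. The last line of each table was incomplete and was left out, which left 34385 and 34396 genes. Of the 34396 gene identifiers, 34356 (99.9%) were found in GENCODE mouse release M21 on GRCm38, from which coordinates were taken. It is not known whether the authors used that release.

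Each value was divided by its column sum and multiplied by 1000000, which gives parts per 1000000 (ppm) of the column. Genes with at least 1 ppm in at least 3 of the 9 libraries of a table were kept (22233 and 20725 genes), and log2(ppm + 1) was fitted with limma 3.58.1 in R 4.3.3. Fold changes are on this scale, which understates the change of low genes. The 3 groups of a table entered 1 fit and shared 1 estimate of the spread, with empirical Bayes moderation and a mean-variance trend. Tests were two-sided, p was adjusted by Benjamini-Hochberg (BH) within each comparison, and 0.05 was the threshold. No test crosses the tables, which were normalized apart. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

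The 6 comparisons, the test, the filter, 34 gene lists of pathways and cell types, most of the alternatives and the rule for named genes were chosen before the data were examined, when the values were taken to be TPM, which sum to 1000000. The rescaling to ppm and the alternatives without single libraries that stood apart, without all libraries numbered 1 and on the deposited values with a pseudocount of 20 were added after. Lists were tested with limma's camera (preset inter-gene correlation 0.01), with BH adjustment over 32 lists. A list with fewer than 3 measured members and the sex-linked list were not tested. A list's p was also computed with a correlation estimated from the data and with fry, which does not compare a list with other genes. Up to 4 members of a described list were named by the smallest unadjusted p. The other named genes were Nmnat1, Nmnat2 and Nmnat3. To these were added genes past the threshold with a mean of at least 5 ppm in the higher group and no overlap between the groups. The 8 with the highest and the 8 with the lowest fold change were taken against a control, and 5 of each for 2 arms. Up to 5 genes past the threshold with the same sign in both arms of a table were taken as well. Clone and predicted gene names were left out. Target genes were also compared by an exact permutation test, which cannot go below 0.1 for 3 against 3.

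Alternatives covered the pseudocount, the filter, the scaling, the fit on 2 groups, the trend, array weights, each library left out in turn and, for the overexpression table, the replicate number as a term. The labels give the overexpression samples numbers but do not say what a number shares. Deviations from the group means correlated at 0.461, 0.285 and 0.139 in the 3 same-numbered pairs of the overexpression arms, each above 0.1. The numbers were therefore treated as pairing these arms. This is uncertain for numbers 2 and 3, since the overexpression columns N1_2 and N2_3 (0.242) and N1_3 and N2_2 (0.165) also correlated above 0.1. The pairs of either arm with the empty vector were not all above 0.1, and numbers were not taken to pair them. Other splits of the 6 libraries of each comparison were counted. The overlap of 2 arms was set beside 40 simulated unchanged groups against the same controls, drawn with the same spread per gene in all groups. Simulated data had 200 changed genes per comparison, drawn from genes with a mean of at least 5 ppm, and the same spread per gene in all libraries. Recovery of lower genes, or with libraries that stand apart, was thus not covered. On these data limma recovered 85.1% of the genes changed by a log2 of 2 for Nmnat1 knockdown and 76.1% for Nmnat2 knockdown. For Nmnat1 and Nmnat2 overexpression it recovered 95.5% and 97.0%. At a log2 of 1 it recovered 19.4%, 13.4%, 68.7% and 64.2% in the same order. Unchanged genes made up 7.69%, 5.34%, 5.82% and 8.76% of the simulated calls. For 2 arms the shares recovered at a log2 of 2 were 82.1% in the knockdown table and 98.5% in the overexpression table.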

Results

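The mRNA content was measured in EGFP-positive cells sorted from mouse retinal explants, electroporated at postnatal day 0.5 and cultured for 3 days. Nmnat1 and Nmnat2 encode nuclear and Golgi-associated enzymes that make NAD from nicotinamide mononucleotide, and the study compared cells in which either gene was knocked down or overexpressed with cells that carried a scramble plasmid or an empty vector. Each of the 6 groups held 3 libraries. The deposited columns summed to between 14.4 and 29.6 times 1000000 units in the knockdown table and between 17.3 and 26.2 times 1000000 in the overexpression table, with 24523 to 28953 and 25752 to 30718 genes above 0, respectively. In genes with 1 annotated transcript most low values lay on steps of single reads, which put the relative depth of the libraries at 0.774 to 1.33 of the median library in the knockdown table and 0.838 to 1.16 in the overexpression table. For a gene with an effective length of 1 kb, 1 ppm stood for about 12.7 to 20.7 and 11.8 to 16.7 reads, respectively. Levels are given in ppm of a column's sum, errors of levels as SD, and log2 fold changes on the log2(level + 1) scale with their SE. Nothing in the labels says that the libraries came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical.

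Replicates correlated at Pearson's r of 0.907 to 0.930 across genes in scramble, 0.942 to 0.954 in Nmnat1 knockdown and 0.896 to 0.982 in Nmnat2 knockdown. In the overexpression table r was 0.963 to 0.975 for the empty vector, 0.952 to 0.975 for Nmnat1 and 0.934 to 0.972 for Nmnat2. Some libraries stood apart. Nmnat2 knockdown library N2_2 lay at 129 on the first principal component (24.4% of the variance), whereas the other 8 libraries of the table lay between -31.2 and -5.83. Genes of any type with a symbol that starts with mt- made up 6.51% of its total and at most 4.67% of theirs. In the overexpression table, whose columns are v1 to v3 for the empty vector and again N1_1 to N2_3, the libraries numbered 1 (v1, N1_1 and N2_1) lay at -24.5, -33.9 and -91.4 on the first component (35.5%) and the other 6 between 4.14 and 50.0. The Y-linked gene Eif2s3y was at 28.9, 15.9 and 39.7 ppm in those 3 libraries. It was at 118 and 119 in the other empty-vector libraries, 122 and 132 in the other Nmnat1 libraries and 57.2 and 43.1 in the other Nmnat2 libraries. Kdm5d and Uty, also Y-linked, were the lowest of their group in v1 and N1_1, but the highest in N2_1, at 38.1 and 30.4 ppm.

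Nmnat1 (ENSMUSG00000028992.13, chromosome 4, 149467572 to 149485202, minus strand, GRCm38) was at 19.0 ± 1.99 ppm in scramble cells (19.1, 20.9 and 17) and at 7.80 ± 0.642 in Nmnat1 knockdown cells (7.37, 8.54 and 7.49; n = 3 each). It was thus 2.44-fold lower with no overlap between the groups (exact permutation p = 0.1, the smallest that 3 against 3 allows). By limma the log2 fold change was -1.18 ± 0.25, with an adjusted p of 0.130, or 0.00410 without library N2_2, and Nmnat1 was lower than in Nmnat2 knockdown cells (-1.16 ± 0.25, adjusted p = 0.0476), where it was at 18.9 ± 4.05. Nmnat2 (ENSMUSG00000042751.14, chromosome 1, 152954993 to 153119261, plus strand) was close to the filter. It was at 2.96 ± 2.91 in scramble cells (6.22, 0.624 and 2.03), 2.02 ± 0.625 in Nmnat1 knockdown cells and 0.927 ± 0.390 in Nmnat2 knockdown cells (1.27, 1.01 and 0.503; exact permutation p = 0.3). With limma the latter difference was -0.79 ± 0.52 (adjusted p = 0.476), so a loss of Nmnat2 mRNA was not detectable at this level, and the label of the Nmnat2 knockdown libraries was not checked by it. Nmnat3 (ENSMUSG00000032456.13, chromosome 9, 98287435 to 98420438, plus strand) was at 1.13 ± 1.01, 2.83 ± 2.21 and 0.750 ± 0.422 in the same groups (exact permutation p = 0.4 and 0.6 against scramble).

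In the overexpression table, Nmnat1 rose from 20.8 ± 1.97 with the empty vector to 19325 ± 7372 ppm in Nmnat1 overexpression cells (27832, 15347 and 14797), a 927-fold ratio of means (log2 9.73 ± 0.21, limma adjusted p = 3.43e-09). Nmnat2 rose from 1.89 ± 0.788 to 21581 ± 1072 in Nmnat2 overexpression cells (log2 12.90 ± 0.24, adjusted p = 8.32e-10). In cells with the other plasmid, Nmnat1 was at 42.4 ± 3.08 in Nmnat2 overexpression (0.99 ± 0.21, adjusted p = 0.0733), and Nmnat2 at 5.23 ± 1.84 in Nmnat1 overexpression (1.10 ± 0.24, adjusted p = 0.122). Both passed without the libraries numbered 1 (adjusted p = 0.000705 and 0.0389). Nmnat3 was at 1.99 ± 0.249 with the empty vector and 0.778 ± 0.638 and 0.995 ± 0.716 in Nmnat1 and Nmnat2 overexpression (exact permutation p = 0.1 and 0.2).

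**Figure D1:**
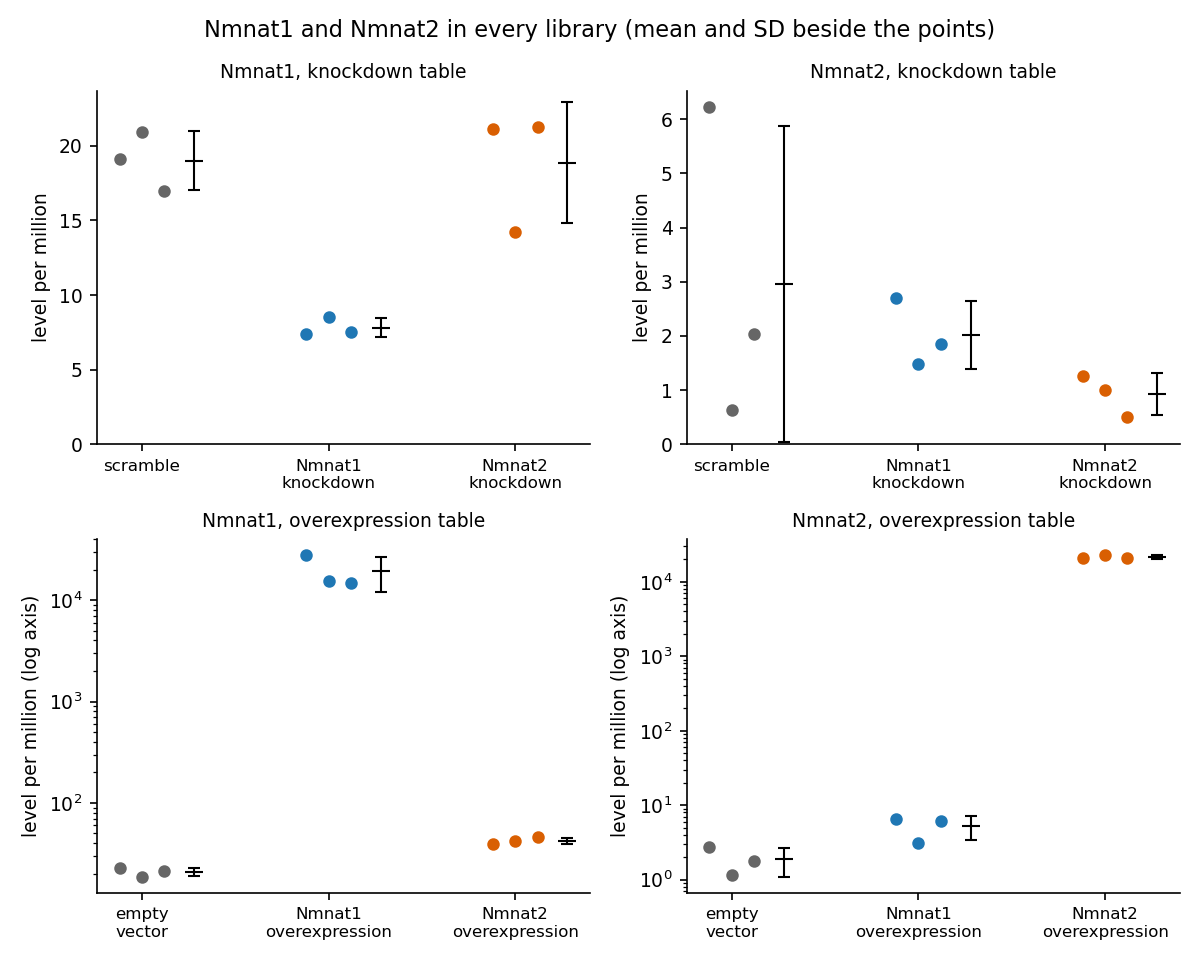
Nmnat1 and Nmnat2 in each of the 18 libraries, as level in ppm, with a linear axis for the knockdown table and a log axis for the overexpression table; points are libraries and bars mean and SD of 3. All 3 Nmnat1 knockdown libraries lie below the scramble libraries for Nmnat1, and for Nmnat2 the knockdown and scramble libraries overlap.

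Nmnat1 knockdown was compared with scramble. Transcripts of the p53 targets Cdkn1a, a cell cycle inhibitor, and Phlda3 rose from 22.8 ± 6.46 to 162 ± 14.6 and from 3.96 to 29.9 ppm (log2 2.81 ± 0.42 and 2.68 ± 0.34, n = 3 per group, limma adjusted p = 0.0437 and 0.0278). The largest rise among the named genes was that of the neuropeptide galanin, Gal, from 0.133 to 17.2 ppm (3.98 ± 0.36, 0.00885). Calb2, which encodes the calcium-binding protein calretinin of amacrine cells, fell from 91.4 ± 6.95 to 15.2 ± 0.977, or 5.70-fold (-2.51 ± 0.27, 0.0176). B2m and H2-D1, components of the class I major histocompatibility complex, fell from 131 to 47.5 and from 189 to 66.0 ppm (-1.45 ± 0.22, 0.0437, and -1.51 ± 0.20, 0.0348).

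Also higher in Nmnat1 knockdown cells were the transcriptional regulators Lmo2 (5.92-fold, 16.8 to 100.4 ppm, adjusted p = 0.0176) and Irf5 (3.55-fold, 19.8 to 71.7, 0.0177), as well as Lrrc38 (3.96-fold, 0.0437), B4galt4 (10.3 to 37.5, 0.0348) and Prob1 (log2 1.55 ± 0.21, 0.0348). The retinoic acid-binding protein gene Crabp1 fell 2.99-fold (120 to 40.1, 0.0437), Gamt, a creatine synthesis enzyme, from 65.1 to 21.9 (0.0348), and Fxyd1 by a log2 of -1.37 ± 0.21 (0.0437). Cox5a, a subunit of cytochrome c oxidase, and the proteasome subunit gene Psmd8 both had a log2 fold change of -1.31 (SE 0.19 and 0.15, 0.0373 and 0.0176). In total 32 of 22233 genes passed, 13 higher and 19 lower, and 2338 had an unadjusted p under 0.05 where 1112 would by chance. The groups did not overlap for 24.8% of genes (10% by chance).

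Among the fixed lists, 11 of 32 passed camera in Nmnat1 knockdown cells. Müller glia genes were lower (median log2 -0.67, adjusted p = 1.18e-08). Of 22 measured, 1 fell over all genes (Crym, -1.20 ± 0.17, 0.0348), and 5 fell when adjusted over the list alone. Apoe (-1.01 ± 0.16, 0.0561) and the glutamine synthetase gene Glul (-0.63 ± 0.17, 0.215) did not pass. The list had adjusted p = 0.455 with an estimated correlation, or 0.0130 without N2_2. Genes of the G2 and M phases were lower (median -0.66, adjusted p = 1.34e-06), and this call held with an estimated correlation (adjusted p = 0.0259). None of the 35 passed over all genes (0 by limma at the adjusted threshold) and 2 fell when adjusted over the list alone. Kif23, a kinesin of cytokinesis, was at -2.06 ± 0.39 (0.0928) and the kinetochore gene Nuf2 at -1.83 ± 0.44 (0.170). Retinal progenitor genes were lower (median -0.68, adjusted p = 4.42e-06), with 0 of 22 past over all genes and 4 lower when adjusted over the list alone. Pax6 was at -1.42 ± 0.30 (0.125) and the Notch effector gene Hes5 at -1.22 ± 0.28 (0.146), and the list had adjusted p = 0.769 with an estimated correlation, or 0.0260 without N2_2. Without N2_2, which belongs to the other arm, 16 Müller glia, 11 progenitor and 2 G2 and M phase genes fell over all genes and none of these lists' genes rose. Adjusted over the list alone, 18, 13 and 3 fell, and 1 Müller glia and 1 progenitor gene rose.

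Amacrine genes were lower in Nmnat1 knockdown cells (median -0.74, adjusted p = 5.15e-06). Of 20 measured, Calb2 fell over all genes, and 7 fell and 1 rose when adjusted over the list alone. Ptf1a, a determinant of amacrine and horizontal fate, was at -2.76 ± 0.58 (0.125) and Nhlh2 at -1.92 ± 0.41 (0.128). This list had adjusted p = 0.455 with an estimated correlation, or 0.0260 without N2_2. The p53 target list was higher (median 0.32, adjusted p = 0.0232), with 2 of 27 higher both over all genes and adjusted over the list alone, Cdkn1a and Phlda3. It had adjusted p = 0.688 with an estimated correlation, and lost its camera call without C2 (0.0847), C3 (0.0750) or N1_3 (0.0580). The pro-apoptotic p53 target Bbc3 was at 0.66 ± 0.26 (0.417). Astrocyte genes were lower (median -0.52, 0.0052), with 0 of 11 past over all genes and 1 lower when adjusted over the list alone (Cxcl14, -1.61 ± 0.29, 0.0875), and adjusted p = 0.358 with an estimated correlation. Without N2_2, 9 amacrine genes fell and 1 rose over all genes (9 and 2 adjusted over the list alone), 8 p53 targets rose and 1 fell (10 and 2), and 3 astrocyte genes fell either way. The p53 and astrocyte lists then had adjusted p = 0.432 and 0.147 with an estimated correlation.

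The other called lists of this comparison had medians between -0.41 and 0.25. Ribosomal protein genes were at -0.16 (0.000189), with 1 of 50 lower over all genes and adjusted over the list alone (Rps2, -1.11 ± 0.17, 0.0437), and adjusted p = 0.855 with an estimated correlation. Cholesterol synthesis genes were at 0.21 (0.00357) with none of 23 past either way and adjusted p = 0.769 with an estimated correlation. Replication-dependent histones were at -0.29 (0.0131; 0 of 18 past over all genes, 1 lower when adjusted over the list alone; adjusted p = 0.358 with an estimated correlation), and had 0.0524 without C2 and 0.0685 without N1_3. Mitochondrially encoded mRNAs were at -0.41 (0.0178; none of 13 past either way; adjusted p = 0.855 with an estimated correlation), with 0.348 without C1, 0.0618 without N1_2 and 0.0685 without N1_3. Unfolded protein response genes were at 0.25 (0.0178). Of its 18 members none passed over all genes and 1 rose and 1 fell when adjusted over the list alone, Xbp1 at 0.84 ± 0.23 (0.222) and Sdf2l1 at -1.06 ± 0.26 (0.172). It had adjusted p = 0.855 with an estimated correlation and 0.0524 by camera without C2. Without N2_2, 9 ribosomal protein, 2 histone and 5 mitochondrially encoded genes fell over all genes, 5 cholesterol synthesis genes rose, and 6 unfolded protein response genes rose and 1 fell. These lists then had adjusted p = 0.267, 0.147, 0.432, 0.147 and 0.147 with an estimated correlation. Neurogenic precursor genes (-0.34, 0.231) passed camera without N2_2 (0.0133; adjusted p = 0.147 with an estimated correlation). The rod (-0.02, 0.606), cone (-0.12, 0.986) and retinal ganglion lists (-0.16, 0.279) did not pass. In the axon injury list (-0.07, 0.830), Gal rose over all genes, and 2 rose and 2 fell when adjusted over the list alone. Microglia genes (0.33, 0.0656) did not pass. Eif2s3y was at 62.9 to 79.3 ppm in Nmnat1 knockdown and 26 to 36.1 in scramble cells. The Y-linked Ddx3y also rose without overlap, but Kdm5d was at 26.8 to 29.5 and 23.5 to 31.7.

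The count for Nmnat1 knockdown rested on which libraries entered the fit. Without N2_2, which belongs to the other arm but shares the estimate of spread, 1802 genes passed (1026 higher, 776 lower), among them all 32. Without C1, C3, N1_1 or N1_2 it was 2, and limma called 0 without C2 or N1_3, where 2007 and 1712 genes had an unadjusted p under 0.05.

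**Figure D2:**
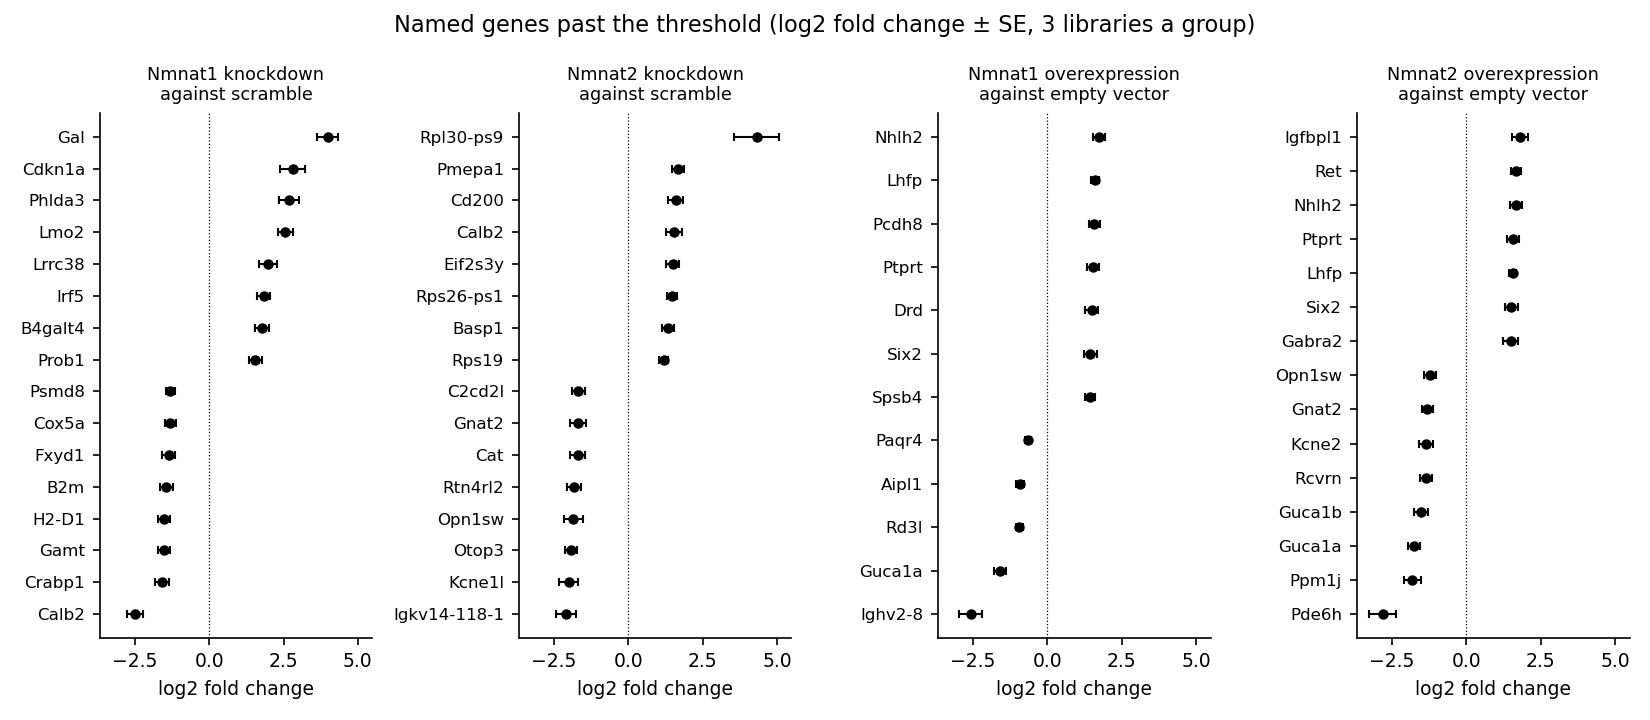
Log2 fold change against the control with SE (x axis) of the genes named for being past the threshold in each of the 4 comparisons with a control, 3 libraries a group; Nmnat1 and Nmnat2 are left out. Gal and Cdkn1a lie highest in Nmnat1 knockdown at 3.98 and 2.81, and Pde6h lies lowest in Nmnat2 overexpression at -2.82.

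Nmnat2 knockdown was compared with the same scramble libraries. In Nmnat2 knockdown cells 4 of 31 measured rod genes and 3 of 16 cone genes fell, and the lists had adjusted p = 0.20 and 0.128 with an estimated correlation. Opn1sw, the short-wavelength cone opsin, fell from 139 to 41.7 ppm (3.61-fold, log2 -1.85 ± 0.32, limma adjusted p = 0.0430, n = 3 per group), and the cone transducin gene Gnat2 from 42.0 to 12 (-1.70 ± 0.28, 0.0379). The rod genes Pde6b (-1.51 ± 0.20, 0.0213), Prph2 (-1.38 ± 0.20, 0.0281), Rdh12 (-1.47 ± 0.25, 0.0382) and Nr2e3, a nuclear receptor of rod fate (1180 to 565 ppm, -1.08 ± 0.17, 0.0336), fell as well. Calb2 rose from 91.4 to 280 ± 103 (1.53 ± 0.27, 0.0484), opposite to its fall in Nmnat1 knockdown. Of 21 measured glycolysis genes, 3 fell, Eno2 (-1.40 ± 0.20, 0.0268), Gpi1 (-0.92 ± 0.15, 0.0379) and Aldoc (-1.22 ± 0.21, 0.0407), and the list had adjusted p = 0.20 with an estimated correlation.

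Further genes higher in Nmnat2 knockdown cells were Pmepa1, an inhibitor of TGF-beta signalling (58.1 to 191 ppm, adjusted p = 0.0213), the surface protein gene Cd200 (26.8 to 80.8, 0.0357), Basp1, a growth cone protein gene (89.9 to 231, 0.0379), and Rps19 (812 to 1872, 0.0213). The Y-linked Eif2s3y, also higher in Nmnat1 knockdown, rose from 32.5 to 92.6 (1.49 ± 0.20, 0.0233) and may mark pup sex. Rpl30-ps9 and Rps26-ps1 (4.32 ± 0.76, 0.0475, and 1.47 ± 0.18, 0.0213) are pseudogenes, whose reads may be split with their parent genes. Further lower genes were Kcne1l (4.03-fold, 195 to 52.8, 0.0336), Otop3 (52.3 to 13.1, 0.0213), Rtn4rl2, a Nogo receptor family gene (47.1 to 12.6, 0.0213), the catalase gene Cat (36.5 to 10.6, 0.0235) and C2cd2l (-1.68 ± 0.23, 0.0213). Igkv14-118-1 (-2.10 ± 0.34) is an immunoglobulin segment with near-identical copies, and its value is uncertain. Crym (544 to 268, 0.0379) and Olfm1 (107 to 217, 0.0379) moved as they did in Nmnat1 knockdown cells, where they went to 236 (0.0348) and 239 (log2 1.15 ± 0.16, 0.0373). In total 97 of 22233 genes passed, 17 higher and 80 lower. This split depended on the scaling, with 66 higher and 33 lower under median-of-ratios scaling (50 of them among the 97) and 64 and 109 under quantile normalization (71 among the 97). An unadjusted p under 0.05 was found for 3742 genes (1112 by chance). The groups did not overlap for 21.9% of genes (10% by chance).

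The median log2 fold change of all genes was -0.23 in Nmnat2 knockdown and moved to -0.05 under median-of-ratios scaling, and the lists are therefore also given relative to it. The rod list was at -0.95, or -0.72 relative to all genes and -0.69 under the other scaling (camera adjusted p = 3.33e-12). Of 31 measured rod genes, 4 fell over all genes, 19 fell when adjusted over the list alone, and none rose. The list had adjusted p = 0.20 with an estimated correlation. Library N2_2 was 0.81 above N2_1 and N2_3 in rod genes, and without it the list was at -1.22 with adjusted p = 0.0027 with an estimated correlation. The cone list was at -0.86, or -0.62 relative to all genes (9.79e-05), with 3 of 16 lower over all genes and 7 adjusted over the list alone, and adjusted p = 0.128 with an estimated correlation (0.0232 without N2_2). Glycolysis genes were at -0.53, or -0.30 relative (0.000432), with 3 of 21 lower over all genes and 8 adjusted over the list alone, and adjusted p = 0.20 with an estimated correlation. G2 and M phase genes were at -0.57, or -0.33 relative (0.00739), with none of 35 past either way and adjusted p = 0.128 with an estimated correlation. Their median was -0.12 under quantile normalization. That list had 0.0524 by camera without C1. Pigment epithelium genes, of which 8 of 15 were measured, were at -0.89, or -0.66 relative (0.00429). None passed over all genes, 4 fell when adjusted over the list alone, with Dct at -1.11 ± 0.25 (0.0883), and the list had adjusted p = 0.128 with an estimated correlation. Without N2_2, 25 rod genes fell and 1 rose over all genes, 9 glycolysis genes fell and 1 rose, and 7 cone, 6 G2 and M phase and 2 pigment epithelium genes fell. The glycolysis, G2 and M phase and pigment epithelium lists then each had adjusted p = 0.138 with an estimated correlation.

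Ribosomal protein genes were higher in Nmnat2 knockdown cells, at 0.53, or 0.76 relative to all genes (adjusted p = 3.37e-31). Rps19 rose over all genes, 25 of 50 rose when adjusted over the list alone, and the list had adjusted p = 0.20 with an estimated correlation. Library N2_2 was 0.56 above the other Nmnat2 knockdown libraries in this list. Amacrine genes were at 0.46, or 0.69 relative (0.000418). Of 20, Calb2 rose over all genes, and 4 rose and 1 fell when adjusted over the list alone, with Gad2, a GABA synthesis enzyme, at 1.25 ± 0.25 (0.0621) and Neurod6 at -1.89 ± 0.38 (0.0633). N2_2 deviated by -1.08 in this list, which had adjusted p = 0.389 with an estimated correlation, or 0.0232 without N2_2. Retinal ganglion genes were at 0.18, or 0.42 relative (0.000418), with 0 of 30 past over all genes, 3 higher when adjusted over the list alone (Uchl1, 0.78 ± 0.18, 0.0951), and adjusted p = 0.128 with an estimated correlation. Axon injury genes were at 0.25, or 0.48 relative (0.00267; none of 18 past either way; adjusted p = 0.315 with an estimated correlation). The growth cone gene Gap43 was at 1.04 ± 0.33 (0.160). Mitochondrially encoded mRNAs were at 0.37 (0.00094; none of 13 past either way; adjusted p = 0.781 with an estimated correlation). N2_2 deviated by 1.55 in that list, which was at -0.15 (camera adjusted p = 0.474) without it. Neurogenic precursor genes were at 0.28, or 0.51 relative (0.00305; none of 21 past either way; adjusted p = 0.788 with an estimated correlation, or 0.0232 without N2_2), with N2_2 at -1.03 and 0.0693 and 0.117 by camera without N2_1 and N2_3. Cholesterol synthesis genes were at -0.35, or -0.12 relative (0.0413; none of 23 past over all genes, 1 lower when adjusted over the list alone; adjusted p = 0.788 with an estimated correlation), with 0.126, 0.0626, 0.0604 and 0.474 by camera without C1, C2, C3 and N2_2, and 0.269 under median-of-ratios scaling. Without N2_2 the medians were 0.35 for ribosomal protein (29 higher and 2 lower over all genes), 0.94 for amacrine (11 and 1), 0.10 for retinal ganglion (7 and 0), 0.43 for axon injury (3 and 0) and 0.66 for neurogenic precursor genes (12 and 1). The ribosomal, ganglion and axon injury lists then each had adjusted p = 0.138 with an estimated correlation. The Müller glia (-0.31, 0.412), progenitor (-0.14, 0.693) and p53 target lists (-0.32, 0.817) did not pass, but their medians rested on N2_2. It lay at -1.0, -0.89 and -0.70 in these lists, N2_1 at 0.06, 0.20 and -0.10, and N2_3 at -0.07, 0.37 and -0.07. Without it the medians were 0.05, 0.24 and -0.03, with 4, 5 and 5 members higher and 4, 3 and 3 lower over all genes. Progenitor genes (0.0241) and, with a median of -0.23 in place of -0.07, oxidative phosphorylation genes (2.46e-07, 19 of 50 lower) then passed camera, with adjusted p = 0.156 and 0.138 with an estimated correlation.

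For Nmnat2 knockdown, limma called 0 genes without any one of C1, C2, C3, N2_1 or N2_3 (3388, 3270, 3104, 3045 and 2786 at an unadjusted p under 0.05). Without N2_2 it called 3331 (1718 higher, 1613 lower), among them all 97.

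**Figure D3:**
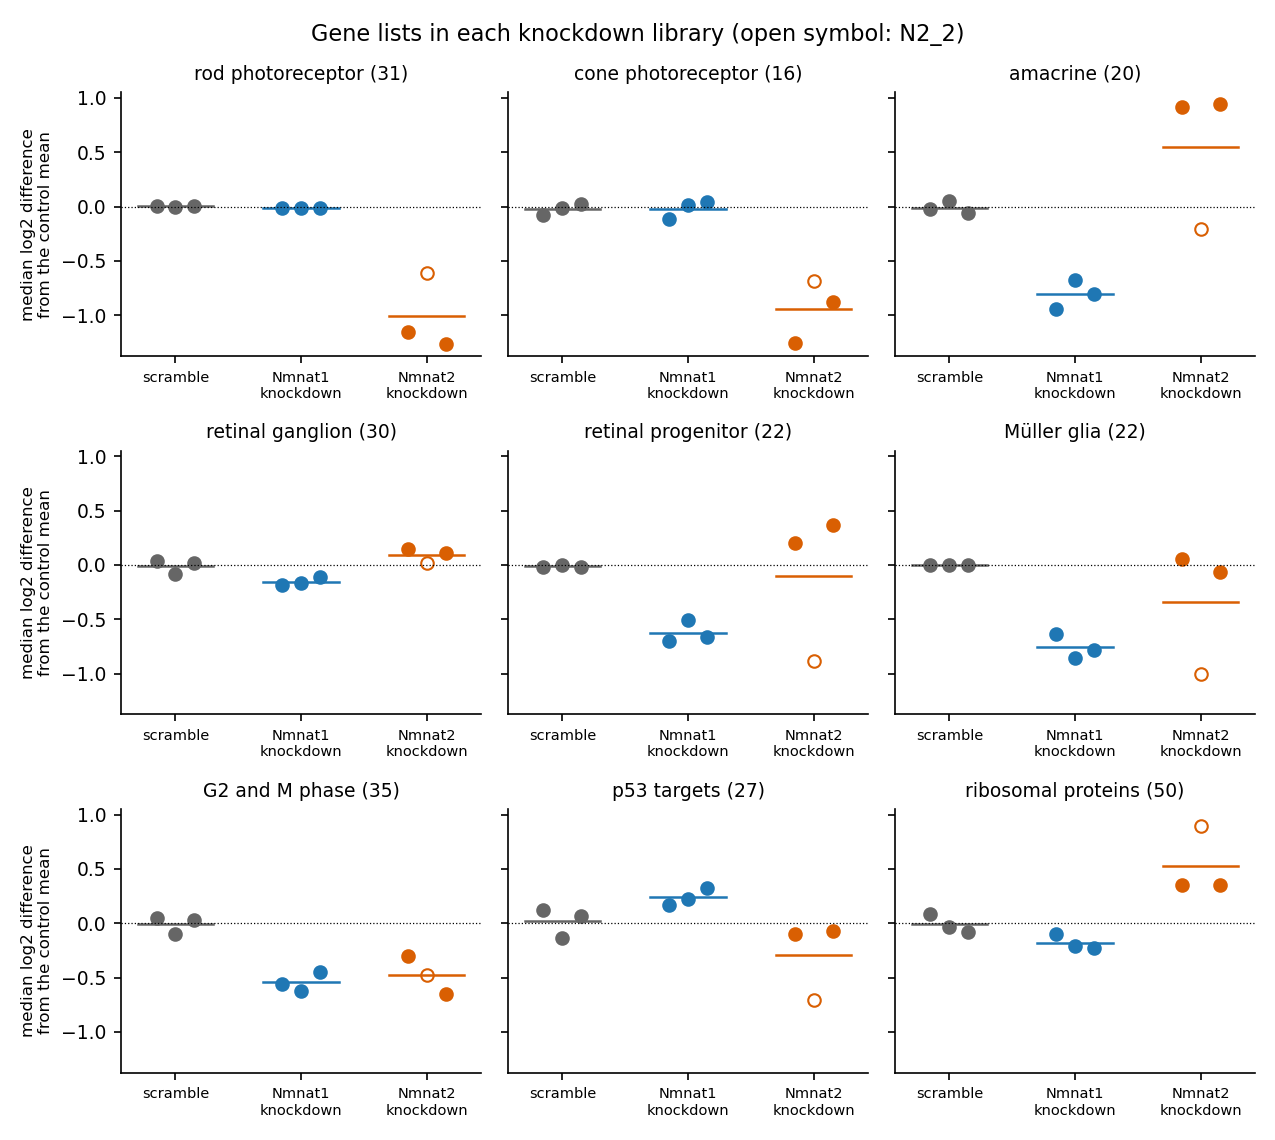
Median log2 difference from the scramble mean (y axis) of 9 gene lists in each of the 9 libraries of the knockdown table; points are libraries, lines group means, and the open symbol is N2_2, which lies apart from N2_1 and N2_3. The rod list of Nmnat2 knockdown lies below that of Nmnat1 knockdown by a median log2 of 1.01.

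The knockdown arms were set against each other, which leaves the scramble libraries out of the difference. Nmnat1 knockdown cells had more of the photoreceptor genes Nr2e3 (log2 1.71 ± 0.17, limma adjusted p = 0.0015), Samd7 (1.71 ± 0.19, 0.00261), Pde6b (1.48 ± 0.20, 0.00645), Otop3 (2.74 ± 0.19, 0.000456) and Gnat2 (1.54 ± 0.28, 0.0226) than Nmnat2 knockdown cells (n = 3 per group). They had fewer transcripts of the amacrine genes Ptf1a (1.19 against 45.9 ppm, -4.24 ± 0.58, 0.00621), Calb2 (15.2 against 280, -4.04 ± 0.27, 0.000456) and Tfap2b (-2.85 ± 0.35, 0.00429). The p53 targets Cdkn1a (162 against 20, 3.20 ± 0.42, 0.00606), Phlda3 (3.11 ± 0.34, 0.00213) and Eda2r (2.10 ± 0.46, 0.0461) were higher in Nmnat1 knockdown cells. So were the matrix metalloproteinase gene Mmp2 (102 against 5.36, 22.9-fold, 0.00832), Kcne1l (507 against 52.8, 10.4-fold, 0.0013) and Gal (3.32 ± 0.36, 0.00199).

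Runx1t1 (-3.20 ± 0.54, 0.0166), the glutamate transporter gene Slc1a6 (-3.09 ± 0.51, 0.0144) and Cd200 (9.31 against 80.8 ppm, 0.000894) were lower in Nmnat1 knockdown cells. In total 458 of 22233 genes passed, 299 higher and 159 lower in Nmnat1 knockdown, with 3656 at an unadjusted p under 0.05 (1112 by chance) and 25.4% not overlapping (10% by chance). The median of all genes was 0.25, or 0.06 under median-of-ratios scaling. That scaling changed the split of calls to 201 higher and 387 lower, and quantile normalization to 348 and 334. For each called list, the value relative to all genes kept its sign under median-of-ratios scaling, and the median kept its sign under quantile normalization.

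The rod list was 1.01 higher in Nmnat1 than in Nmnat2 knockdown cells, or 0.76 relative to all genes (camera adjusted p = 4.96e-13), with 8 of 31 higher over all genes and 18 adjusted over the list alone. The cone list was 0.70 higher, or 0.45 relative (0.00028), with 4 of 16 higher over all genes and 5 adjusted over the list alone. They had adjusted p = 0.134 and 0.129 with an estimated correlation, or 0.00175 and 0.0169 without N2_2. Amacrine genes were at -1.11, or -1.36 relative (1.90e-11), with 6 of 20 lower over all genes and 8 adjusted over the list alone, and adjusted p = 0.129 with an estimated correlation, or 0.0076 without N2_2. Retinal ganglion genes were at -0.11, or -0.35 relative (1.26e-05). Of 30, 5 fell over all genes, among them Stmn2 (-2.02 ± 0.29, 0.00826) and Elavl3 (-2.08 ± 0.31, 0.00874), 9 were lower and 2 higher when adjusted over the list alone, and the list had adjusted p = 0.129 with an estimated correlation. Ribosomal protein genes were at -0.68, or -0.93 relative (3.84e-43), with 13 of 50 lower over all genes, 40 adjusted over the list alone, and adjusted p = 0.129 with an estimated correlation. Glycolysis genes were at 0.68, or 0.43 relative (0.000561). Of 21, 6 were higher and 1 lower over all genes, 10 and 2 adjusted over the list alone, with the lactate dehydrogenase gene Ldha at 1.19 ± 0.13 (0.00209) and Eno2 at 1.75 ± 0.20 (0.0031), and the list had adjusted p = 0.188 with an estimated correlation. Without N2_2, 26 rod and 7 cone genes were higher over all genes and 10 amacrine, 9 retinal ganglion and 36 ribosomal protein genes lower, while 9 glycolysis genes were higher and 2 lower. The medians were then 1.34, 0.94, -1.55, -0.16, -0.52 and 0.41, and the ganglion, ribosomal and glycolysis lists had adjusted p = 0.0767, 0.0527 and 0.164 with an estimated correlation.

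Cholesterol synthesis genes were 0.74 higher in Nmnat1 knockdown cells, or 0.49 relative (3.66e-06). Of 23, Mvk (1.05 ± 0.19, 0.0232), Fdps (0.74 ± 0.16, 0.0439) and Msmo1 (0.85 ± 0.18, 0.0459) were higher over all genes, 9 were when adjusted over the list alone, and the list had adjusted p = 0.242 with an estimated correlation. Progenitor genes were at -0.36, or -0.61 relative (1.83e-06), with Pax6 (-2.10 ± 0.30, 0.00726) and Six3 (-1.09 ± 0.20, 0.0239) lower over all genes, 4 lower and 1 higher of 22 when adjusted over the list alone, and adjusted p = 0.385 with an estimated correlation, or 0.00829 without N2_2. Müller glia genes were at -0.31, or -0.56 relative (1.55e-05), with 0 of 22 past over all genes, 2 lower when adjusted over the list alone, and adjusted p = 0.385 with an estimated correlation, or 0.0076 without N2_2. Neurogenic precursor genes were at -0.46, or -0.71 relative (2.88e-05), with Sox11 (-1.59 ± 0.26, 0.0144) lower over all genes, 4 lower and 2 higher of 21 when adjusted over the list alone, and adjusted p = 0.424 with an estimated correlation, or 0.00829 without N2_2. N2_2 deviated by -1.09 in the progenitor and Müller glia lists. Mitochondrially encoded mRNAs were at -0.68, or -0.92 relative (1.91e-08), with 0 of 13 past over all genes, 1 lower when adjusted over the list alone, and adjusted p = 0.329 with an estimated correlation. N2_2 lay at 1.40 from the scramble mean in this list and N2_1 and N2_3 both at -0.15, and without N2_2 the median was -0.26 (camera adjusted p = 0.00128, with 2 lower over all genes, and adjusted p = 0.442 with an estimated correlation). Without N2_2 the cholesterol list was at 0.49 (7 higher; adjusted p = 0.0819 with an estimated correlation). The progenitor list was at -0.92 (15 lower, 1 higher), the Müller glia list at -0.70 (13 and 1) and the neurogenic precursor list at -0.62 (15 and 2).

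Of the remaining called lists of this comparison, histones were at -0.19, or -0.44 relative (0.00297), with Hist1h2bc (-1.66 ± 0.33, 0.0316) lower over all genes, 2 of 18 lower when adjusted over the list alone, and adjusted p = 0.129 with an estimated correlation. The pigment epithelium list was at 0.54, or 0.30 relative (0.00941), with Tyrp1 (2.20 ± 0.30, 0.00619) and Dct (1.33 ± 0.25, 0.0248), both melanin synthesis genes, as the 2 of 8 higher over all genes and adjusted over the list alone, and adjusted p = 0.129 with an estimated correlation. Unfolded protein response genes were at 0.51, or 0.27 relative (0.0390), with Xbp1 (1.22 ± 0.23, 0.0254) higher over all genes, 5 of 18 adjusted over the list alone, and adjusted p = 0.667 with an estimated correlation. The p53 target list was at 0.37, or 0.12 relative (0.0499), with 3 of 27 higher over all genes and 7 adjusted over the list alone, and adjusted p = 0.392 with an estimated correlation. Without N2_2, 2904 genes passed (1396 higher, 1508 lower), among them all 458, but the camera calls of the histone (0.290, median -0.05), unfolded protein response (0.415, 0.13) and p53 lists (0.232, 0.40) were lost. In these lists 3, 1 and 3 genes were then lower over all genes and 1, 4 and 7 higher. The pigment epithelium list had adjusted p = 0.162 with an estimated correlation. Oxidative phosphorylation (0.25, 3.09e-06, 20 higher and 3 lower), interferon response (0.62, 0.0328, 2 higher, and 0 adjusted over the list alone by limma) and S phase genes (-0.08, 0.0225, 6 lower) passed camera without N2_2, with adjusted p = 0.164, 0.179 and 0.164 with an estimated correlation. The camera calls of the unfolded protein response were also lost without N1_1 (0.0904) or N1_2 (0.0641), and those of the p53 list without N1_1 (0.0515), N1_2 (0.0573) or N1_3 (0.0605). Under median-of-ratios scaling they were at 0.103 and 0.0768. Leaving out N1_1, N1_2, N1_3, N2_1 or N2_3 gave 106, 89, 80, 187 and 175 genes.

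The knockdown arms share their scramble libraries, which by itself makes their fold changes correlate. Across 22233 genes, which are not independent replicates, r was 0.49 (rho 0.447), and 0.50 on average in 40 simulations of unchanged groups against the same controls. The covariance was 0.180 against a simulated 0.106. Without N2_2, r was 0.47 (0.45 simulated) and the covariance 0.199 (0.0812). By direction, 1 gene was higher and 4 lower in both, where independent lists would share 0.00994 and 0.0684. Without N2_2, 363 were higher and 243 lower in both (79.3 and 56.3 by independence), and 205 were opposite (134). Of the shared genes, Olfm1 and Crym were named above, and Calb2 moved in opposite directions. With 3 control libraries the controls could not be split, and part of the excess may come from them. The simulations also gave all groups the same spread per gene. Scramble replicates correlated less well (r of 0.907 to 0.930) than those of Nmnat1 knockdown (0.942 to 0.954), so the simulated covariance may be too low.

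Nmnat1 overexpression was compared with the empty vector. Besides Nmnat1, genes of the amacrine and retinal ganglion lists were among those that rose, and rod genes among those that fell. Nhlh2, a transcription factor gene of the amacrine list, rose from 30.2 to 104 ppm (log2 1.75 ± 0.20, limma adjusted p = 0.0141, n = 3 per group), the protocadherin gene Pcdh8 from 16.8 to 51.9 (1.58 ± 0.19, 0.0167) and Ina, which encodes the neurofilament protein internexin, from 18.3 to 41.5 (1.13 ± 0.17, 0.0421). Guca1a, a calcium-sensing activator of photoreceptor guanylate cyclase (chromosome 17, 47394558 to 47400584), fell from 153 to 49.1 (-1.60 ± 0.20, 0.0192). Aipl1, a chaperone of photoreceptor phosphodiesterase, fell from 94.7 to 49.4 (-0.93 ± 0.13, 0.0340).

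Lhfp (41.8 to 130 ppm, 0.000772), the receptor phosphatase gene Ptprt (12.6 to 39.0, 0.0267), Six2 (7.41 to 21.7, 0.0340) and Spsb4 (20 to 55.2, 0.0141) were also higher. So was the gene listed as Drd (ENSMUSG00000021478.6, Drd1 in GENCODE M21, a dopamine receptor gene), at 31.7 against 10.6 (0.0352). Rd3l (-0.94 ± 0.11, 0.0159) and Paqr4 (-0.66 ± 0.10, 0.0353) were lower, and the immunoglobulin segment Ighv2-8 (-2.58 ± 0.39, 0.0421) is uncertain because it has near-identical copies. In total 25 of 20725 genes passed, 19 higher and 6 lower (8 and 1 under median-of-ratios scaling, all among the 25), with 1983 at an unadjusted p under 0.05 (1036 by chance) and 17.8% not overlapping (10% by chance).

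The rod list was lower in Nmnat1 overexpression cells (median -0.82, camera adjusted p = 3.30e-23). Of 30 measured, Guca1a and Aipl1 were the 2 that fell over all genes, and 21 fell when adjusted over the list alone, with the recoverin gene Rcvrn at -1.25 ± 0.21 (0.0581). The list had adjusted p = 0.278 with an estimated correlation, and 0.0335 without the libraries numbered 1 (median -1.07). The cone list was lower (median -0.62, 2.51e-12), which held with an estimated correlation (adjusted p = 0.0359) but not without the libraries numbered 1 (0.0835), which leaves 2 libraries a group and a median of -0.68. None of 16 passed over all genes and 10 fell when adjusted over the list alone, with Gnat2 at -1.14 ± 0.19 (0.0581). Amacrine genes were higher (median 0.87, 1.87e-08), with Nhlh2 higher over all genes and 8 of 20 adjusted over the list alone. Calb2 was at 1.52 ± 0.24 (0.0525) and Gad2 at 2.04 ± 0.37 (0.0720), and the list had adjusted p = 0.278 with an estimated correlation. Retinal ganglion genes were higher (median 0.41, 1.02e-06), which held with an estimated correlation (adjusted p = 0.0435) but not without the libraries numbered 1 (0.0835, with a median of 0.40), with Ina of 28 higher over all genes, 6 adjusted over the list alone, and Ebf3 at 1.44 ± 0.24 (0.0581). Without the libraries numbered 1, 26 rod genes fell and 1 rose over all genes, 7 cone genes fell, 12 amacrine genes rose, and 10 retinal ganglion genes rose and 1 fell. The amacrine list then had a median of 1.18 and adjusted p = 0.0835 with an estimated correlation.

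Immediate early genes were lower in Nmnat1 overexpression cells (median -0.30, 0.00673), with 0 of 17 past over all genes and Egr1 (-1.06 ± 0.17, 0.0565) as the 1 that fell when adjusted over the list alone. This list had adjusted p = 0.158 with an estimated correlation and 0.0579 by camera without v2. Müller glia genes were at 0.29 (0.00124; none of 23 past either way) and progenitor genes at 0.29 (0.00166; 0 of 22 past over all genes, 2 higher when adjusted over the list alone), and ribosomal protein genes at 0.11 (4.08e-05; 0 of 50 over all genes, 1 higher when adjusted over the list alone). Each of the 3 had adjusted p = 0.625 with an estimated correlation, and the progenitor list had 0.0895 by camera without N1_2. Genes of the integrated stress response were at -0.25 (0.0356; none of 25 past either way), glycolysis genes at -0.10 (0.0210; 0 of 21 over all genes, 3 lower when adjusted over the list alone) and nuclear oxidative phosphorylation genes at -0.09 (0.0286; none past either way). They had adjusted p = 0.494, 0.494 and 0.625 with an estimated correlation. Under median-of-ratios scaling their camera calls were lost (0.0688, 0.0673 and 0.332). The call of the stress response was also lost without v1 (0.0666), v2 (0.107), N1_1 (0.0707) or N1_3 (0.0936), that of glycolysis without v2 (0.0552), v3 (0.0611) or N1_1 (0.117), and that of oxidative phosphorylation without v2 (0.0807), v3 (0.186) or N1_1 (0.379). When the libraries numbered 1 were left out, 6 immediate early genes fell over all genes and 8 Müller glia genes rose. Of progenitor genes 11 rose and 1 fell, of ribosomal protein genes 7 and 2, of stress response genes 1 and 3, and of both glycolysis and oxidative phosphorylation genes 2 and 6. The call of glycolysis was lost (0.0671, median -0.09). Neurogenic precursor (0.20, 0.000684), G2 and M phase (-0.33, 0.0292) and mitochondrially encoded genes (-0.10, 0.0121) passed camera. None of these 10 lists passed with an estimated correlation. The p53 list (-0.12, 0.714) did not pass.

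Without N1_1, 271 genes passed for Nmnat1 overexpression (122 higher, 149 lower), and without all 3 libraries numbered 1, 1666 did (918 higher, 748 lower), among them all 25. Leaving out v1, v2, v3, N1_2 or N1_3 gave 15, 4, 3, 4 and 3.

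Nmnat2 overexpression was compared with the same empty-vector libraries. In Nmnat2 overexpression cells 8 of 30 measured rod genes and 6 of 16 cone genes fell, and the lists had adjusted p = 0.201 and 0.0136 with an estimated correlation. The cone phosphodiesterase gene Pde6h fell from 14.7 to 1.25 ppm (log2 -2.82 ± 0.46, limma adjusted p = 0.0323, n = 3 per group), Guca1a from 153 to 44.9 (-1.76 ± 0.20, 0.0145), its neighbour Guca1b (chromosome 17, 47385393 to 47392967) from 68.3 to 23.6 (-1.52 ± 0.24, 0.0266) and Rcvrn from 156 to 60.2 (-1.37 ± 0.21, 0.0258). Gnat2 fell from 54.0 to 21.4 (-1.33 ± 0.19, 0.0198) and Opn1sw from 187 to 78.7 (-1.23 ± 0.20, 0.0323). The receptor tyrosine kinase gene Ret rose from 12.3 to 41.1 (1.67 ± 0.16, 0.0054) and Nhlh2 from 30.2 to 97.4 (1.65 ± 0.20, 0.0164).

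Igfbpl1 (4.08 to 17 ppm, 0.0253), Ptprt (12.6 to 40.4, 0.0173), Lhfp (41.8 to 125, 0.00102), Six2 (1.52 ± 0.20, 0.0174) and Gabra2, a GABA receptor subunit gene (1.48 ± 0.26, 0.0464), were also higher, and Ppm1j (-1.82 ± 0.28, 0.0258) and Kcne2 (-1.35 ± 0.23, 0.0397) lower. In total 114 of 20725 genes passed, 42 higher and 72 lower, with 2132 at an unadjusted p under 0.05 (1036 by chance) and 16.3% not overlapping (10% by chance).

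Rod genes were lower in Nmnat2 overexpression cells (median -0.89, camera adjusted p = 7.13e-31), with 8 of 30 lower over all genes, among them Aipl1 (-1.13 ± 0.13, 0.0145) and Samd11 (-0.92 ± 0.13, 0.0195), and 24 adjusted over the list alone. The list had adjusted p = 0.201 with an estimated correlation, and 0.0223 without the libraries numbered 1 (median -0.97). Cone genes were lower (median -0.77, 1.35e-17), which held with an estimated correlation (adjusted p = 0.0136) but not without the libraries numbered 1 (0.0572, with a median of -0.66), with 6 of 16 lower over all genes, among them Ccdc136 (-0.74 ± 0.09, 0.0145) and Gnb3 (-0.69 ± 0.10, 0.0258), and 11 adjusted over the list alone. Retinal ganglion genes were higher (median 0.43, 2.09e-05), with Ina (0.97 ± 0.17, 0.0414) and Ebf3 (1.30 ± 0.24, 0.0498) as the 2 of 28 higher over all genes, 4 adjusted over the list alone, and adjusted p = 0.0766 with an estimated correlation. Amacrine genes were higher (median 0.76, 4.35e-05), with Nhlh2 and Calb2 (1.30 ± 0.24, 0.0488) as the 2 of 20 higher over all genes, 8 adjusted over the list alone, and adjusted p = 0.435 with an estimated correlation. When the libraries numbered 1 were left out, 25 rod and 6 cone genes fell over all genes and 12 retinal ganglion and 11 amacrine genes rose. The last 2 lists then each had adjusted p = 0.0741 with an estimated correlation.

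Nuclear oxidative phosphorylation genes were lower in Nmnat2 overexpression cells by a small median (-0.16, 3.55e-11), with Cox8a (-0.55 ± 0.09, 0.0359) of 50 lower over all genes, 6 adjusted over the list alone, and adjusted p = 0.201 with an estimated correlation. Glycolysis genes were at -0.11 (0.000133), with Gpi1 (-0.74 ± 0.12, 0.0356) and Aldoa (-0.72 ± 0.13, 0.0481) as the 2 of 21 lower over all genes, 5 adjusted over the list alone, and adjusted p = 0.255 with an estimated correlation. That list had 0.0543 by camera without N2_1. Genes of the integrated stress response were at -0.16 (0.0447; none of 25 past either way; adjusted p = 0.435 with an estimated correlation), and had 0.0690, 0.103 and 0.292 by camera without v1, v2 and N2_1. The list had 0.440 (median -0.09) without the libraries numbered 1, where 8 oxidative phosphorylation genes fell over all genes, while 5 glycolysis genes fell and 1 rose. Müller glia (0.34, 2.97e-10), progenitor (0.36, 8.44e-08), neurogenic precursor (0.22, 0.0207), G2 and M phase (-0.35, 3.99e-05) and mitochondrially encoded genes (-0.16, 4.69e-05) then passed camera, with adjusted p = 0.0572, 0.0741, 0.452, 0.0741 and 0.292 with an estimated correlation. Without N2_1, 301 genes passed (159 higher, 142 lower), and without all 3 libraries numbered 1, 1222 did (678 higher, 544 lower), among them all 114. Leaving out v1, v2, v3, N2_2 or N2_3 gave 13 (10 higher, 3 lower), 5, 3, 4 and 4, in each case with more genes higher than lower.

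**Figure D4:**
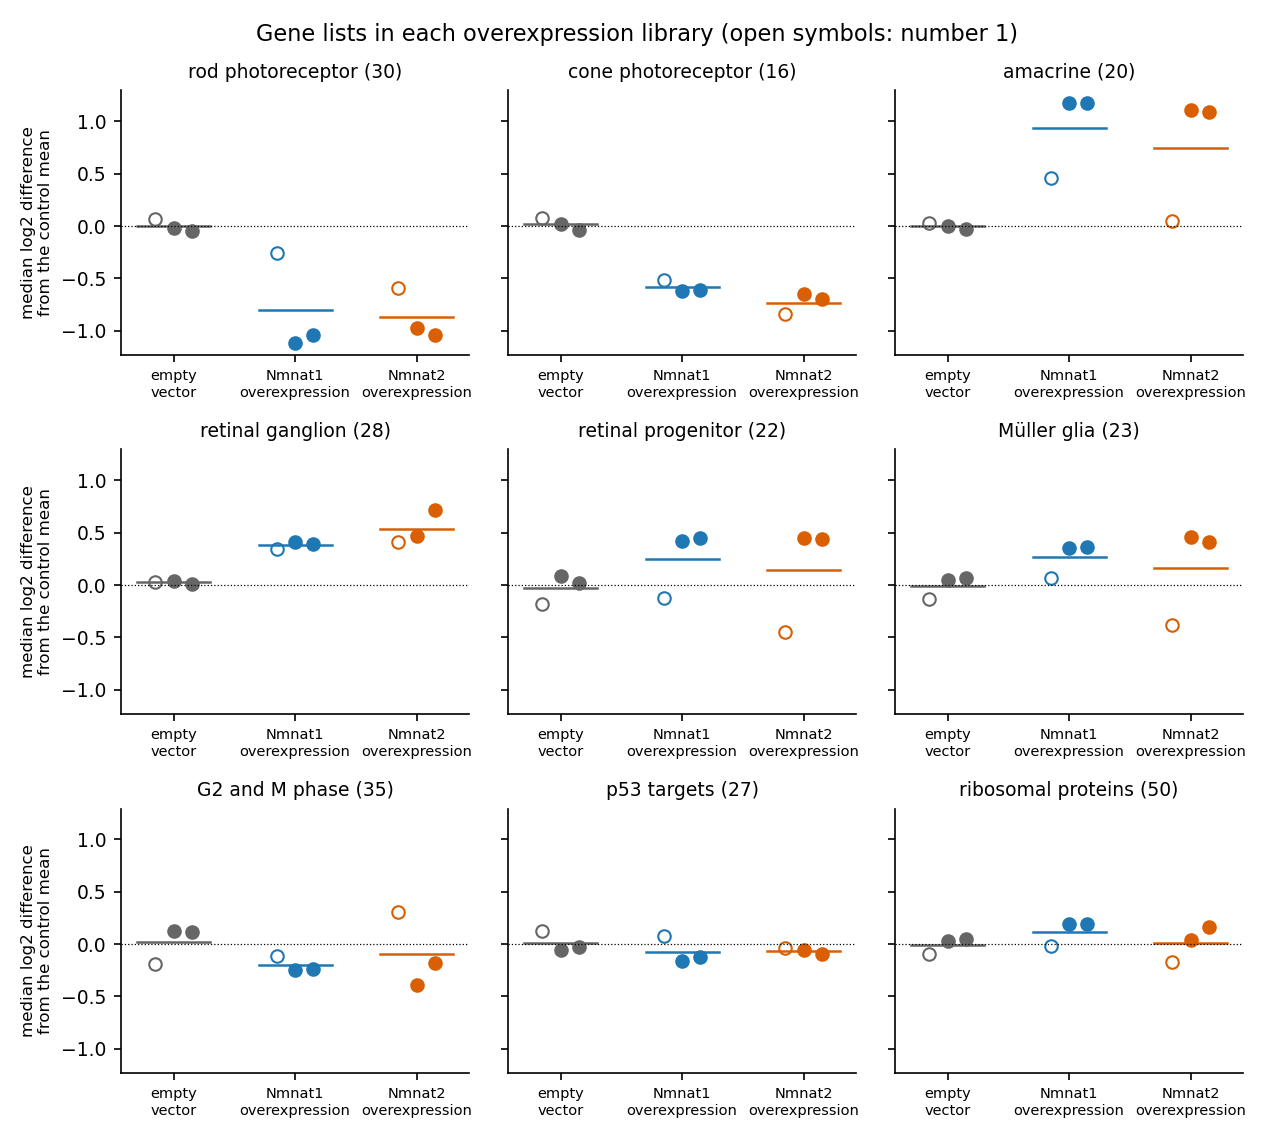
Median log2 difference from the empty-vector mean (y axis) of 9 gene lists in each of the 9 libraries of the overexpression table; points are libraries, lines group means, and open symbols the libraries numbered 1. The medians of the rod list are -0.82 in Nmnat1 and -0.89 in Nmnat2 overexpression.

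The overexpression arms differed in 4 genes, 2 higher and 2 lower in Nmnat1 overexpression (2 and 1 under median-of-ratios scaling). These were Nmnat1 (log2 8.74 ± 0.21, limma adjusted p = 5.26e-09), Nmnat2 (-11.81 ± 0.24, 2.1e-09), Cyr61, a secreted matricellular protein gene (10.4 ppm in Nmnat1 against 31.3 in Nmnat2 overexpression cells, -1.51 ± 0.19, 0.0480), and the predicted gene Gm6563 (ENSMUSG00000051255.5, 1.28 ± 0.14, 0.0145). Gm6563 lies outside the naming rule and was chosen after its values were seen, 60.6, 68.9 and 66.9 against 32.4, 23.6 and 24.0 ppm. An unadjusted p under 0.05 was found for 924 genes (1036 by chance), and 8.34% did not overlap (10% by chance). Without the libraries numbered 1, 38 genes passed (19 higher, 19 lower), and without N2_1 or N1_1 alone 11 and 9. Without N1_3, N2_2 or N2_3, 2 passed. Libraries of the same number deviated together in these arms, most clearly those numbered 1 (r = 0.461), but N1_2 and N2_3 did as well (0.242). With the number as a block 4 genes passed and 1814 had an unadjusted p under 0.05. Cyr61 was no longer among them (-1.51 ± 0.19, 0.0791), and the immediate early gene Fos was, at 51.2 in Nmnat1 against 117 ppm in Nmnat2 overexpression cells (-1.18 ± 0.10, 0.00594, against ± 0.37 and 0.953 without the block).

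Of the lists, 6 passed camera between the overexpression arms, none with a member of its own past the threshold by limma, and none with an estimated correlation. Higher with Nmnat1 were oxidative phosphorylation (median 0.08, 9.39e-08), ribosomal protein (0.12, 4.72e-07), rod (0.13, 0.00294), cone (0.22, 0.00452) and heat shock genes (0.11, 0.00943), and lower were immediate early genes (-0.15, 0.0496), where Egr1 was at -1.32 ± 0.17 (0.0518). In this order they had adjusted p = 0.358, 0.922, 0.923, 0.358, 0.358 and 0.358 with an estimated correlation. The oxidative phosphorylation and ribosomal medians moved with the scaling, to 0.16 and 0.21 under median-of-ratios scaling and 0.03 and 0.07 under quantile normalization. With the replicate number as a block glycolysis (0.08), neurogenic precursor (0.12) and amacrine genes (0.18) passed camera as well, each with an adjusted p of 0.0351, but had adjusted p = 0.729, 0.929 and 0.929 with an estimated correlation. The camera calls of the rod (0.283, with the median at -0.10) and cone lists (0.141) were lost without N1_1, and those of the heat shock (0.106) and ribosomal lists (0.382) without N2_1. The rod call was also lost without N2_2 (0.0634) or N2_3 (0.0818) of the overexpression table, and the immediate early call without N1_1 (0.115), N1_3 (0.0777), N2_2 (0.171) or N2_3 (0.132), or under median-of-ratios scaling (0.0919). Without all libraries numbered 1 the rod (0.487, median 0.01), cone (0.257, 0.04) and heat shock calls (0.102, 0.13) were lost, amacrine genes passed camera (0.15, 0.00849; adjusted p = 0.524 with an estimated correlation), and 2 immediate early genes were lower over all genes.

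Both overexpression arms shared 16 higher and 5 lower genes, where independent lists would share 0.0385 and 0.0208. These included Nhlh2, Lhfp, Ptprt, Six2 and Guca1a. Without the libraries numbered 1, 498 were higher and 360 lower in both (30 and 19.6 by independence), and 4 were opposite (48.6). The fold changes correlated across 20725 genes at r = 0.52 (0.50 in the simulations), with a covariance of 0.0927 against a simulated 0.0711. Without the libraries numbered 1, r was 0.57 (0.50) and the covariance 0.144 (0.0549). Here too the controls could not be split. The simulated groups share the controls but not the deviations common to libraries of the same number, and part of the excess may come from either. Knockdown and overexpression of the same gene, compared across 19711 genes of both tables without a test, had r of -0.0943 (rho -0.0604) for Nmnat1 and -0.0264 (rho -0.0341) for Nmnat2. For Nmnat1 no gene past the threshold by limma was shared. Without N2_2, 0 again moved the same way (0.924 higher and 0.231 lower by independence) and 16 were opposite (1.00). For Nmnat2, 1 was higher and 9 were lower in both, where 0.0336 and 0.292 would be by independence, and 1 was opposite (0.220). Without N2_2, 13 were higher and 54 lower in both (3.40 and 5.80 by independence), and 2 were opposite (9.41). Gnat2 and Opn1sw were among the genes that fell in both. Knockdown of one gene and overexpression of the other gave correlations farther from 0. For Nmnat1 knockdown and Nmnat2 overexpression r was -0.147 (rho -0.174), and without N2_2 46 genes were opposite (5.20 by independence). For Nmnat2 knockdown and Nmnat1 overexpression r was 0.222 (rho 0.262), or 0.283 without N2_2, where 7 genes were higher and 5 lower in both (1.57 and 0.483).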

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

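The tests of the scramble libraries, of library N2_2 and of the sex of the pups for the rod genes of Nmnat2 knockdown, and the levels of microglia genes and the relative depth in N2_2, were chosen only after the results were seen.

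In the knockdown table, 4 lists moved in opposite directions in the knockdown arms, and camera called the difference between the arms for each. Amacrine genes had a median of -0.74 in Nmnat1 and 0.46 in Nmnat2 knockdown (difference -1.11), ribosomal protein genes -0.16 and 0.53 (-0.68), cholesterol synthesis genes 0.21 and -0.35 (0.74), and mitochondrially encoded mRNAs -0.41 and 0.37 (-0.68). With an estimated correlation the differences had adjusted p of 0.129, 0.129, 0.242 and 0.329 by camera. For the mitochondrially encoded mRNAs, the value in Nmnat2 knockdown was -0.15 without N2_2, so that this opposite movement rested on that library. For cholesterol synthesis genes it was -0.13 without N2_2 and did not pass.

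Library N2_2 stood apart from N2_1 and N2_3, with mitochondrially encoded mRNAs 1.55 and rod genes 0.81 above them on the log2 scale, oxidative phosphorylation genes 0.76 above, and Müller glia, progenitor, amacrine and neurogenic genes between -1.09 and -1.03. A bias by transcript length or GC content stays open: the deviation correlated with length at a Spearman rho of -0.151, and another library reached 0.165. Its relative depth was 0.846, with 2 scramble or Nmnat1 knockdown libraries lower (lowest 0.774), which argues against fewer reads as the source. The SD of its deviation over well-expressed genes, 0.969, was 1.84 times that of the most variable of those groups' libraries. This fell short of the bound of over 2 times set in advance, and so did not decide. Fewer starting molecules stay open. Cells of another type may have been sorted along, as the microglia and macrophage list was 1.15 above the other Nmnat2 libraries, past the bound of 1 set in advance, although the EGFP gate would remove untransfected cells. The 16 measured genes of this list summed to 71.4 ppm in N2_2 against 23.8 to 71.3 in the other 8 libraries, and it was the highest library for 5 of them, with Cd68 at 12 (0 to 3.57 elsewhere), Laptm5 at 10.4 (0.632 to 5.25) and Fcer1g at 9.05 (0 to 4.93), but C1qa, the most abundant on average over the 9 libraries, was at 1.5 against 3.15 to 10, so that this explanation also stays open.

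Photoreceptor genes were lower in Nmnat2 knockdown by camera, with a rod median of -0.95 (adjusted p = 0.20 with an estimated correlation). Scramble libraries that were high by chance would leave no difference between the knockdown arms, but this was 1.01 (adjusted p = 0.134 with an estimated correlation). Library N2_2 was not the source, since without it the median was -1.22 (adjusted p = 0.0027 by camera with an estimated correlation). For the sex of the pups, Nmnat1 knockdown was as far above scramble in sex-linked genes (0.80 ± 0.14, against 0.77 ± 0.10 in Nmnat2 knockdown, SD, n = 3) and had a rod median of -0.0239, which argues against it as the source. Eif2s3y and Ddx3y were above scramble without overlap in both knockdown arms, but Kdm5d and Uty overlapped. The list is thus an unsure measure of sex and does not exclude it. An effect of Nmnat2 knockdown itself is a hypothesis that no value here tests, since a loss of Nmnat2 mRNA was not detectable.

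Photoreceptor genes were lower in both overexpressions by camera, but with an estimated correlation the rod lists had adjusted p = 0.278 and 0.201 in Nmnat1 and Nmnat2 overexpression, and the cone calls that held (0.0359 and 0.0136) were lost without the libraries numbered 1 (0.0835 and 0.0572), where the cone medians were -0.68 and -0.66 and had been -0.62 and -0.77. The libraries numbered 1 were not the source, since without them the rod medians were -0.97 in Nmnat2 and -1.07 in Nmnat1 overexpression. The Nmnat1 and empty-vector libraries left were alike in Y-linked level, which argues against pup sex in that arm. For Nmnat2 sex stays open, with Eif2s3y at 57.2 and 43.1 ppm against 118 and 119. Empty-vector libraries that are high by chance stay open: with each left out in turn the rod median lay between -0.947 and -0.764 over both arms, but all 3 are shared by them. A shared effect of the enzymes was not tested and stays open.

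For none of the 6 comparisons are there enough splits of the libraries (10) for a share under 0.05. The real split gave 32, 97, 458, 25, 114 and 4 genes for Nmnat1 and Nmnat2 knockdown, their direct comparison, Nmnat1 and Nmnat2 overexpression and theirs. The highest of the other splits gave 1, 2, 2, 1, 4 and 6, and the splits with as many genes as the real one, itself included, numbered 1, 1, 1, 1, 1 and 2. If the overexpression arms are paired by number, which is uncertain for numbers 2 and 3, the split with 6 parts only 1 pair. Of the 3 other splits that part all 3 pairs as the real one does, the highest then gave 1. Without pairing, the split with 6 exceeds the real 4.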

How the results depend on the processing

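The fits without the 3 libraries numbered 1 and on the deposited values with a pseudocount of 20 were chosen only after the data were seen. Counts of genes past the limma threshold follow for Nmnat1 knockdown (32), Nmnat2 knockdown (97) and their direct comparison (458), and for Nmnat1 overexpression (25), Nmnat2 overexpression (114) and theirs (4). Only settings that moved a count by over 1.5 times, or its split between higher and lower, are printed, not each with its split. The cause was not tested unless given. A pseudocount of 0.1 gave 17 for Nmnat1 knockdown. Without a filter, which adds low genes to the tests, the counts were 14 and 32 in Nmnat1 and Nmnat2 knockdown and 16 and 48 in Nmnat1 and Nmnat2 overexpression. With a filter of 5 ppm, which tests fewer genes, they were 190 in Nmnat2 knockdown and 54 and 181 in the overexpressions. Median-of-ratios scaling gave 9 in Nmnat1 overexpression (8 higher, 1 lower, where 19 and 6 were) and 71 in Nmnat2 overexpression, and split 99 of Nmnat2 knockdown into 66 higher and 33 lower, where 17 and 80 were. Quantile normalization gave 113 and 173 (64 higher, 109 lower) in the knockdowns and 42 in Nmnat1 overexpression. The fit on the 2 groups alone, which leaves out N2_2 for Nmnat1 knockdown, gave 969, 0 (2932 at an unadjusted p under 0.05), 108 and, for the overexpression arms, 2. Without the trend limma called 1, 0 (3776 unadjusted), 162, 2 and 5 for the first 5 comparisons. Array weights, which weight down libraries that stand apart, gave 868, 5101, 6072, 1540, 1251 and 25. The deposited values, with a pseudocount of 20, gave 2, 0 (2597 unadjusted), 17, 1, 59 (7 higher, 52 lower) and 2. Without the libraries numbered 1 the overexpression counts were 1666, 1222 and 38. Leaving out 1 library in turn gave 0 to 1802, 0 to 3331 and 80 to 2904 in the knockdown table, each highest without N2_2, and 3 to 271, 3 to 301 and 2 to 11 in the overexpression table, each highest without a library numbered 1. No paired analysis was possible for the knockdown table because its columns are not tied to numbered samples. In the overexpression table, 7 of 9 same-numbered pairs of libraries correlated above 0.1 in their deviations (0.0271 to 0.461, other pairs -0.378 to 0.242), and 5 of 9 libraries correlated best with their own number, so the numbers were not taken to pair either arm with the empty vector. They were treated as pairing the 2 arms, although N1_2 and N2_3, of different numbers, correlated at 0.242. With the replicate block, fitted over all 9 libraries, the counts were 187 and 269 for Nmnat1 and Nmnat2 overexpression and 4 between the arms, of which 3 are the same genes. Between the arms the block changed the calls of Cyr61, Fos and 3 lists given with that comparison, and no other. No named gene that passed, with or without an alternative, turned in direction. Called lists, tested with camera in each refit, turned in 3 of 1051 values, none past the threshold. They were the mitochondrially encoded mRNAs in Nmnat2 knockdown without N2_2 (adjusted p = 0.474 by camera, and 3.46e-07 at the lowest with 1 library left out) and with array weights (0.982), and the rod list between the overexpression arms without N1_1 (0.283, and 1.08e-07 at the lowest). Of 313 values of named genes, those that lost the threshold numbered 11 with a pseudocount of 0.1, 10 with 5, 48 without a filter, 41 with median-of-ratios scaling, 15 with quantile normalization, 59 in the fit on 2 groups, 98 without the trend, 0 with array weights and 101 on the deposited values, and 509 of 1938 values did when 1 library was left out. These values include named genes that had not passed in the main fit and could not lose the threshold, so the share of calls lost is larger. Of 62 called lists, 58 lost the call with an estimated correlation, 39 with fry, 12 with array weights, 8 with quantile normalization and 7 with median-of-ratios scaling, and 49 of 383 values did when 1 library was left out, besides 2 that turned. With the replicate block 2 of 24 lists did, both of the integrated stress response (adjusted p = 0.0615 and 0.0786 by camera), and without the libraries numbered 1, 5 of 24. Depth limits the lowest genes, since at 1 ppm, the filter, a gene with an effective length of 1 kb rests on about 11.8 to 20.7 reads.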

Other observations

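The list tests were planned, and the sequence shared by Nmnat1 and Nmnat2 transcripts was looked up only after the levels of both genes were seen.

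The lists closest to the enzymes themselves did not pass camera in any of the 6 comparisons. NAD metabolism genes had medians between -0.17 and 0.22 (smallest adjusted p = 0.236), and none of their members passed over all genes. Among them, the mitochondrial NAD kinase gene Nadk2 was at 38.7 ppm in Nmnat2 knockdown against 70.7 in scramble (-0.97 ± 0.33, limma adjusted p = 0.184), and the ectonucleotidase gene Nt5e at 120 in Nmnat2 overexpression against 184 with the empty vector (-0.63 ± 0.17, 0.172). NAD consuming enzymes had medians between -0.16 and 0.30 (smallest 0.0942). The 1 member that passed was the deacetylase gene Sirt2, at 126 in Nmnat1 against 71.2 in Nmnat2 knockdown (0.82 ± 0.17, 0.0418). Sirt3 was at 48.1 and 50.5 in Nmnat2 and Nmnat1 overexpression against 69.8 with the empty vector (-0.53 ± 0.12, 0.1, and -0.46 ± 0.12, 0.190).

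Other lists that passed in none of the 6 comparisons were apoptosis regulators (medians -0.24 to 0.11, smallest adjusted p = 0.512), interferon response (-0.44 to 0.51, 0.112), S phase (-0.19 to 0.08, 0.0732), bipolar (-0.56 to 0.34, 0.227), horizontal (-0.29 to 0.44, 0.298), microglia and macrophage (-0.32 to 0.48, 0.0656), endothelium and pericyte (-0.35 to 0.22, 0.0909) and lens genes (-0.54 to 0.35, 0.693), all by camera. Without N2_2, interferon response (0.0328) and S phase genes (0.0225) passed between the knockdown arms. For several uncalled lists of the direct knockdown comparison, among them axon injury, heat shock and apoptosis, the median and the camera test differed in sign.

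Nmnat1 was at 39.4, 42.4 and 45.6 ppm in the Nmnat2 overexpression libraries and at 22.6, 18.7 and 21.3 with the empty vector. The annotated transcripts of Nmnat1 and Nmnat2 share 1 stretch of 31 bases, which lies in a dinucleotide repeat. In the direct knockdown comparison, Kcne1l was at 507 ppm in Nmnat1 and 52.8 in Nmnat2 knockdown, with scramble between them at 195.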
